A study of Mus musculus with 207 samples.

How the data were processed

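Total RNA of jejunum (70 libraries), liver (70) and hypothalamus (67) from C57BL/6 mice was sequenced, and each library carried a label with its tissue, diet and mouse identifier. The labels name an RNeasy kit for jejunum and liver and Tri-reagent for hypothalamus, and do not give the sex of the mice, a batch or a date. Per the submitters' processing notes, the tools were cutadapt, FastQC, Trim Galore 0.61, STAR and DESeq2 1.24.0 with the mouse build GRCm38. The strand setting, the annotation release and the STAR version were not given in the sources used here.

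For jejunum and liver the authors deposited counts, that is, unscaled whole reads per gene over 55536 genes. Non-gene entries of those tables (reads that were unmapped, matched several places, matched no gene or were ambiguous) were left out of library sizes, and reads that matched several places came to 8.00% in jejunum and 7.70% in liver of all entries. For hypothalamus the deposited unit was a signal, the count divided by 1 size factor per library, over 21883 genes. Every positive hypothalamus value lay within 0.05 of a whole read (100%) once multiplied by a factor recovered from the values, and these factors ran from 0.712 to 1.08. Libraries held 17.5 to 23.8 M reads on genes in jejunum, 21.0 to 41.0 M in liver and 14.4 to 16.1 M in hypothalamus. No pair of columns was identical.

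Libraries were grouped by tissue and diet label alone, which gave 18 groups. The comparisons, tests, gene lists, rule for naming genes and first set of alternatives were fixed before the data were examined. In jejunum and liver, genes were kept by filterByExpr (minimum count 10, minimum total 15), scaled by TMM and tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with 1 coefficient per diet and no covariate. The same edgeR test had been planned for hypothalamus. Because its table held scaled values, limma 3.58.1 with a trend was used there on log2(value + 1) for genes with a value of at least 10 in at least 10 libraries, and edgeR on the recovered reads became an alternative. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in that tissue and comparison were called. The 9 comparisons per tissue were not adjusted for one another. Group means are given in counts per M (CPM) or, for hypothalamus, in reads after division by size factors.

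A set of 57 gene lists, written from general knowledge, was tested with camera (preset inter-gene correlation 0.01, adjusted over the lists of 1 comparison). Beside it stand the same test with an estimated correlation and the number of members called over all genes and with p adjusted over the list alone. Of the list results that camera called, 8 of 154 in jejunum, 2 of 100 in liver and 1 of 60 in hypothalamus passed also with the estimated correlation. Genes were named by a rule with 3 parts: up to 6 with the largest positive and 6 with the largest negative log2 fold change among called genes with an average of at least 1 CPM, up to 3 members of each list with the smallest adjusted p, and 4 reference genes per tissue. Members of some lists stand without their list's counts for length. Results of a few genes that the rule selected are not reported here, and some called genes that moved by over 1.5 times without 1 library, or changed direction under an alternative, are not named. Gene coordinates, lengths and GC content came from GENCODE M21 transcripts on GRCm38.

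The tests were run on libraries simulated from the measured means and spreads, with folds placed in genes. For WPI against CAS at FAT-55, folds of 1.25, 1.5, 2 and 4 were recovered for 36%, 66%, 84% and 96% of changed genes in jejunum, 55.1%, 78%, 89.8% and 98% in liver and 32%, 55.1%, 86% and 100% in hypothalamus. False calls were 5.45%, 2.76% and 6.83% of all calls there, and 1.94%, 7.69% and 4.07% for FAT-55 against FAT-20 on CAS. Real libraries may do worse, as random splits of them called up to 9903 hypothalamus genes.

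The first alternatives were DESeq2 1.42.0, median-of-ratios scaling, no filter on low counts, sums over mice whose identifiers share a stem (the identifier without its last digit, 24 stems per tissue), a random effect for stem, sample quality weights, and covariates from markers of neighbouring tissue. For hypothalamus they were run on recovered reads or, where the test was limma, on log values. The consensus correlation within a stem was 0.114 in jejunum, 0.16 in liver and 0.34 in hypothalamus. What a stem stands for is not stated in the labels. Identifiers were used as printed: 1 stem is spelled differently in hypothalamus (CAS FAT-55 replicates 9 to 11) than in jejunum and liver (replicates 1 and 2), and 1 CAS FAT-20 identifier carries another library number in liver than in the other tissues. The 74 identifiers, the 63 with all tissues and the pairing of tissues depend on that reading. Alternatives added later were other pseudocounts (0.5 and 10), edgeR on recovered reads, removal of each library's GC and length trend, removal of libraries with low correlation to the others (under 0.97 in hypothalamus, the least similar library in jejunum and liver), removal of the hypothalamus library with most intestinal transcripts, and covariates for adipose and smooth muscle markers or clock genes. Every count was also set against 100 splits of the libraries, the real one included.

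Reads that match several places are not in the counts, so values of near-identical paralogs, such as defensin, serum amyloid, globin and Cyp2b genes, rest on the unique part of their reads. Without the strand setting, reads of overlapping genes on opposite strands cannot be assigned with certainty. Body weight, microbiota and other data of the study were not analysed here.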

Results

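Gene expression was measured by RNA sequencing in jejunum, liver and hypothalamus of C57BL/6 mice that had eaten 1 of 6 diets. The diets crossed 2 protein sources, labelled CAS and WPI, with 3 fat levels, labelled FAT-20, FAT-40 and FAT-55, and every diet carried the protein level 30. CAS and WPI are read here as casein and whey protein isolate from knowledge of the study, because the labels give only the abbreviations and no unit for either level. The series title asks how the kind and amount of protein alter what dietary fat does to body weight and tissue partitioning. The 207 libraries came from 74 mouse identifiers, 63 of them with all 3 tissues. Groups held 10 to 12 libraries each, namely 11, 12 and 11 for CAS and 12, 12 and 12 for WPI at FAT-20, FAT-40 and FAT-55 in jejunum and liver, and 10, 12, 11, 11, 11 and 12 in hypothalamus. In each tissue WPI was compared with CAS, averaged over fat and at each fat level, and FAT-55 and FAT-40 were compared with FAT-20 on each protein. A further contrast tested whether the change from FAT-20 to FAT-55 differed between WPI and CAS. Values beside gene names are log2 fold changes ± standard error (SE) with Benjamini-Hochberg adjusted p over all genes tested in that tissue, from edgeR in jejunum and liver and from limma in hypothalamus. Coordinates are those of GRCm38 in GENCODE M21. For gene lists the counts are of members measured in that tissue.

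**Figure D1:**
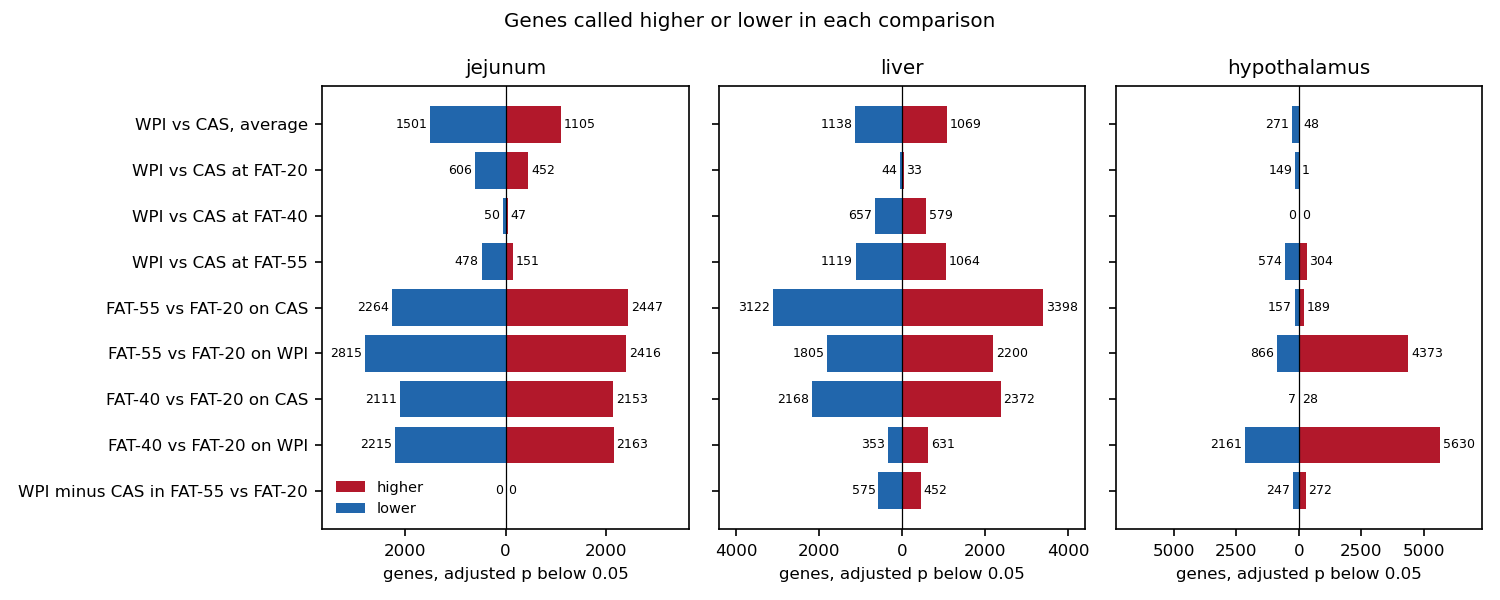
Number of genes with adjusted p under 0.05 (horizontal axis) that were higher or lower in each of the 9 comparisons, with 1 panel per tissue. The jejunum comparison of FAT-55 with FAT-20 on CAS gave 2447 higher and 2264 lower genes, and the difference between WPI and CAS in that response gave 0 in jejunum and 1027 in liver.

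Averaged over the 3 fat levels, jejunum held less mRNA for mucosal defence and lymphocytes on WPI than on CAS. Pigr (ENSMUSG00000026417, chromosome 1, 130826684 to 130852249), the receptor that carries IgA across the epithelium, fell (-0.97 ± 0.07, adjusted p = 6.2e-17) and lay below the CAS median of the same fat level in 36 of 36 WPI libraries. At FAT-55 its mean was 2090 ± 298 CPM (SD, n = 12) on WPI against 4580 ± 799 (SD, n = 11) on CAS. Ccl28, a chemokine that draws IgA plasma cells to mucosa (-0.92 ± 0.09, adjusted p = 8.4e-13), Lypd8, a protein that keeps bacteria off the epithelium (-0.43 ± 0.05, adjusted p = 5.2e-09), Reg3g, an antibacterial lectin (-1.19 ± 0.30, adjusted p = 0.003), and Ceacam10 (-3.35 ± 0.28, adjusted p = 1.2e-14, 36 of 36 libraries below the CAS median) fell as well. Of the antimicrobial peptides and epithelial defence genes 2 of 23 rose and 13 fell (4 and 15 over the list alone, camera adjusted p = 7.5e-11, 0.0041 with estimated correlation). T cell and cytotoxic lymphocyte genes fell, with Lck at -0.64 ± 0.09, Cd3g at -0.58 ± 0.08 and Zap70 at -0.56 ± 0.08. Of the T cell genes 16 of 18 fell and 0 rose (17 and 0 over the list alone, camera adjusted p = 7.5e-18, 0.028 with estimated correlation). Of the B and plasma cell genes 17 of 17 fell and 0 rose (17 and 0 over the list alone, camera adjusted p = 1.5e-11, 0.2 with estimated correlation). Ighm (-1.55 ± 0.26) and Fcer2a (-3.51 ± 0.62) lay below the CAS median in 28 and 27 of 36 libraries. Whether the pieces differed in lymphoid tissue was not tested.

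Antigen presentation and interferon genes were also lower on WPI. Of the MHC class II genes 8 of 8 fell and 0 rose (8 and 0 over the list alone, camera adjusted p = 9e-07, 0.22 with estimated correlation), with H2-Aa at -0.45 ± 0.11 and H2-DMb2 at -1.45 ± 0.27. Among interferon response genes 23 of 47 fell and 0 rose (25 and 0 over the list alone, camera adjusted p = 4.1e-11, 0.34 with estimated correlation), including the nucleic acid sensor Zbp1 (-1.02 ± 0.16, adjusted p = 1.5e-06), Psmb8 (-0.45 ± 0.08) and Nlrc5 (-0.50 ± 0.10).

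Some metabolic genes were higher on WPI. Ces2a, a carboxylesterase (0.92 ± 0.13, adjusted p = 2.5e-07, 33 of 36 libraries above the CAS median), and Cyp2c29, a cytochrome P450 (1.89 ± 0.29, adjusted p = 1.2e-06), led the xenobiotic and glutathione metabolism genes, of which 18 of 29 rose and 0 fell (20 and 0 over the list alone, camera adjusted p = 7.5e-13, 0.2 with estimated correlation). For cholesterol synthesis 19 of 25 rose and 0 fell (20 and 0 over the list alone, camera adjusted p = 5.2e-13, 0.18 with estimated correlation), with mevalonate kinase Mvk at 0.41 ± 0.07 and Insig1 at 0.43 ± 0.09. Of the fat absorption and chylomicron assembly genes 9 of 26 rose and 0 fell (14 and 0 over the list alone, camera adjusted p = 8.7e-09, 0.34 with estimated correlation), among them the acyl-CoA synthetase Acsl3 (0.64 ± 0.10) and the lipid droplet coat Plin2 (0.24 ± 0.06). Cpt1a, which brings fatty acids into mitochondria, rose (0.14 ± 0.04, adjusted p = 0.0054). Srebf1, the regulator of fatty acid synthesis (0.73 ± 0.11, adjusted p = 1e-06), the sugar transporter Slc5a4b (0.49 ± 0.08) and the kinase Mylk3 (1.74 ± 0.16, adjusted p = 8.6e-13) rose. The peptide transporter Slc15a1 (0.07 ± 0.08, adjusted p = 0.64) and the apolipoprotein Apoa4 (0.34 ± 0.13, adjusted p = 0.056) did not pass. Over all genes 1105 were higher and 1501 lower of 16992 tested. Sums by identifier stem gave 1250 genes in place of 2606.

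At FAT-20 WPI lowered Saa1, an acute phase protein that the gut makes against bacteria (-4.04 ± 0.64, adjusted p = 1.5e-05), which lay below the CAS median of 2.32 CPM in 11 of 12 libraries. CAS FAT-20 replicate 1 held 56.6 CPM of Saa1, and without it the log2 ratio of group means was -2.28 in place of -4.05 (-5.01 without WPI FAT-20 replicate 9). Fabp6, the ileal bile acid binding protein, was called higher (5.65 ± 0.91, adjusted p = 2.2e-05), but its mean rested on WPI FAT-20 replicates 9 and 1 with 282 and 177 CPM, and without them the log2 ratio of means was -0.17 (6.39 in place of 5.65 without CAS FAT-20 replicate 1). T cell genes fell, with Cd3e at -0.75 ± 0.15. Among all T cell genes 14 of 18 fell and 0 rose (16 and 0 over the list alone, camera adjusted p = 3.6e-20, 0.014 with estimated correlation). Macrophage genes followed, where 12 of 19 fell and 0 rose (15 and 1 over the list alone, camera adjusted p = 7.8e-13, 0.016 with estimated correlation), with Csf1r at -0.56 ± 0.12 and Cd14 at -0.67 ± 0.15. In antimicrobial defence 1 of 23 rose and 10 fell (2 and 14 over the list alone, camera adjusted p = 3.1e-09, 0.012 with estimated correlation). Fasn (0.72 ± 0.17), Acaca (0.49 ± 0.11) and Srebf1 (0.94 ± 0.19) rose among lipogenic genes, of which 6 of 23 rose and 0 fell (10 and 1 over the list alone, camera adjusted p = 8.6e-06, 0.032 with estimated correlation). In all 452 genes were higher and 606 lower, against 227 genes in total when counts were summed by identifier stem.

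Fewer genes passed at FAT-40, where 47 were higher and 50 lower. Ceacam10 was lower (-2.79 ± 0.48, adjusted p = 0.00031), the nitric oxide pathway enzyme Ddah1 was higher (1.35 ± 0.23, adjusted p = 0.00031) and Mvk was higher (0.48 ± 0.12, adjusted p = 0.045). Tm4sf4 rose as well (1.18 ± 0.21). Reg3g (0.60 ± 0.51, adjusted p = 0.67) and Slc15a1 (0.17 ± 0.14, adjusted p = 0.64) did not pass. Sums by identifier stem left 12 genes.

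At FAT-55 the defence genes were lower on WPI, with Reg3g at -2.71 ± 0.55, adjusted p = 0.0014 and a mean of 48.4 ± 33.1 CPM against 316 ± 434 on CAS. Without CAS FAT-55 replicate 11 (1550 CPM) the log2 ratio of means was -1.99. Pigr (-1.13 ± 0.12) and Ccl28 (-0.98 ± 0.15) fell. Of the list 9 of 23 fell and 0 rose (14 and 1 over the list alone, camera adjusted p = 3.2e-11, 0.0037 with estimated correlation). Defensins of Paneth cells, the granulated cells of the crypt base, were lower as well, among them Defa34 (-2.03 ± 0.46). Of the Paneth cell genes 9 of 17 fell and 0 rose (13 and 0 over the list alone, camera adjusted p = 5.1e-08, 0.38 with estimated correlation). Of the B and plasma cell genes 11 of 17 fell and 0 rose (14 and 0 over the list alone, camera adjusted p = 1e-09, 0.3 with estimated correlation). Acsl3 (1.05 ± 0.18), the glutathione transferase Gsta3 (1.19 ± 0.28) and Mylk3 (2.06 ± 0.28) rose. A total of 151 genes were higher and 478 lower, and sums by identifier stem left 65. Reads of defensin, serum amyloid, globin and immunoglobulin segment genes may be split among near-identical copies, so values of single members are uncertain.

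**Figure D2:**
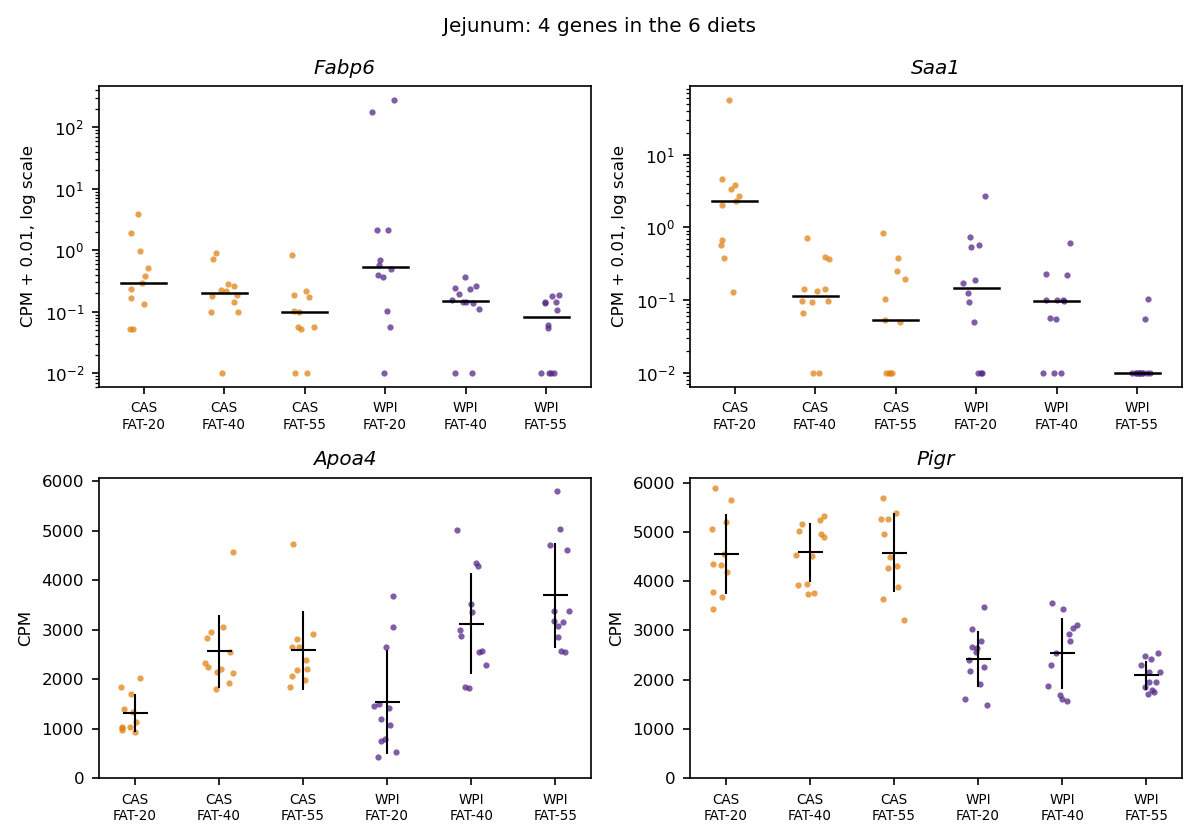
CPM of Fabp6 and Saa1 (log scale, 0.01 added, lines at medians) and of Apoa4 and Pigr (bars give the mean ± SD) in the 6 diets, with 1 point per jejunum library and 11 or 12 libraries per diet. Pigr was lower on WPI at each fat level, and Apoa4 was higher at FAT-40 and FAT-55 than at FAT-20.

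On CAS, FAT-55 against FAT-20 raised genes that take up and export fat in the jejunum. Apoa4, a chylomicron apolipoprotein (ENSMUSG00000032080, chromosome 9, 46240696 to 46243459), rose (0.97 ± 0.23, adjusted p = 0.0011) to a mean of 2590 ± 793 CPM (SD, n = 11) from 1320 ± 385 (SD, n = 11), and 11 of 11 FAT-55 libraries lay above the FAT-20 median. The fatty acid receptor Cd36 (1.03 ± 0.17, adjusted p = 7.3e-06), the lysosomal lipase Lipa (0.99 ± 0.15, adjusted p = 3.6e-06) and the phospholipid enzyme Lpcat3 (0.41 ± 0.07, adjusted p = 4.6e-06) rose. Of the fat absorption list 20 of 26 rose and 0 fell (22 and 0 over the list alone, camera adjusted p = 7.8e-13, 0.49 with estimated correlation). Every measured gene of nuclear-encoded oxidative phosphorylation was called, where 61 of 61 rose and 0 fell (61 and 0 over the list alone, camera adjusted p = 1.9e-21, 0.49 with estimated correlation). Ces2a (1.23 ± 0.23), malic enzyme Me1 (2.0 ± 0.25), the retinol carrier Rbp2 (1.13 ± 0.18) and the amino acid transporter Slc6a20a (1.03 ± 0.16) were higher. Enteroendocrine genes rose, among them Chga (0.49 ± 0.08), the incretin Gip (0.64 ± 0.11) and secretin Sct (0.53 ± 0.10). Of the enteroendocrine genes 10 of 20 rose and 0 fell (10 and 0 over the list alone, camera adjusted p = 1.3e-05, 0.047 with estimated correlation).

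Saa1 fell (-5.35 ± 0.75, adjusted p = 4.1e-07, or a log2 ratio of means of -3.64 without CAS FAT-20 replicate 1 and -6.16 without CAS FAT-55 replicate 11), as did Reg3g (-2.61 ± 0.56, adjusted p = 4e-04, or -3.33 without CAS FAT-55 replicate 11), whereas its relative Reg3a rose (1.5 ± 0.23, adjusted p = 3e-06). Defa29 (-1.96 ± 0.50) and Mptx2 (-1.95 ± 0.45) fell among Paneth cell genes, where 1 of 17 rose and 9 fell (1 and 11 over the list alone, camera adjusted p = 5e-05, 0.55 with estimated correlation). Cholesterol genes fell, with squalene epoxidase Sqle at -0.92 ± 0.21. Of the cholesterol synthesis genes 12 of 25 fell and 0 rose (13 and 0 over the list alone, camera adjusted p = 0.00029, 0.55 with estimated correlation). The amylase Amy1 (-1.90 ± 0.35) and the immunoglobulin transcripts Igha (-0.97 ± 0.21) and Igkc (-0.91 ± 0.20) were lower. Fat cell markers fell with the higher fat level, where 5 of 7 fell and 0 rose (5 and 0 over the list alone, camera adjusted p = 0.0016, 0.49 with estimated correlation). Smooth muscle markers, Myl9 at -0.67 ± 0.21 and Synpo2 at -0.56 ± 0.15, also fell. Of the smooth muscle genes 7 of 10 fell and 0 rose (9 and 0 over the list alone, camera adjusted p = 0.00029, 0.55 with estimated correlation). The mean log2 CPM of the adipose markers was 2.49 ± 1.16 (SD, n = 11) at FAT-20 and -0.51 ± 1.12 (SD, n = 11) at FAT-55, and that of smooth muscle 6.49 ± 0.29 and 5.81 ± 0.60. In all 2447 genes were higher and 2264 lower, and 1185 were called when both marker scores entered the model.

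On WPI the same contrast raised Apoa4 (1.26 ± 0.22, adjusted p = 1.5e-05, 12 of 12 libraries above the FAT-20 median), Lipa (1.2 ± 0.15) and Cd36 (1.12 ± 0.16). Of the fat absorption list 19 of 26 rose and 0 fell (22 and 0 over the list alone, camera adjusted p = 2.7e-14, 0.37 with estimated correlation). Oxidative phosphorylation genes rose, where 27 of 61 rose and 0 fell (32 and 0 over the list alone, camera adjusted p = 5.2e-09, 0.52 with estimated correlation), and Me1 (1.69 ± 0.24) and Gip (0.62 ± 0.11) were higher. Reg3g (-3.86 ± 0.57) and its relative Reg3b (-3.54 ± 0.53) fell. Of the Paneth cell list 1 of 17 rose and 14 fell (1 and 16 over the list alone, camera adjusted p = 4.5e-08, 0.38 with estimated correlation), with Defa29 at -3.39 ± 0.51. Cholesterol synthesis genes fell, with Mvk at -0.68 ± 0.12. Among all cholesterol synthesis genes 1 of 25 rose and 18 fell (2 and 20 over the list alone, camera adjusted p = 1.1e-07, 0.37 with estimated correlation). Fatty acid synthase Fasn was -1.11 ± 0.17 and Amy1 was -2.30 ± 0.33. For adipose markers 6 of 7 fell and 0 rose (6 and 0 over the list alone, camera adjusted p = 0.00096, 0.37 with estimated correlation), and for smooth muscle markers 10 of 10 fell and 0 rose (10 and 0 over the list alone, camera adjusted p = 1.2e-08, 0.37 with estimated correlation).  Altogether 2416 genes were higher and 2815 lower, and 255 with the adipose and smooth muscle scores in the model.

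FAT-40 against FAT-20 on CAS raised Apoa4 (0.96 ± 0.23, adjusted p = 0.0014), the fatty acid transporter Slc27a4 (0.58 ± 0.10), Chga (0.41 ± 0.08) and Gip (0.60 ± 0.11). Reg3g (-2.58 ± 0.54) and the fucosyltransferase Fut2 (-0.96 ± 0.17) fell. Of genes induced when amino acids are short (asparagine synthetase Asns -0.80 ± 0.13, Psat1 -0.94 ± 0.15) 2 of 29 rose and 14 fell (2 and 15 over the list alone, camera adjusted p = 0.00056, 0.48 with estimated correlation). Tagln (-1.01 ± 0.20) and the smooth muscle (6.49 to 5.64) and adipose scores (2.49 ± 1.16 to -0.77 ± 0.32 log2 CPM) fell. Here 2153 genes were higher and 2111 lower, and 177 with both scores in the model.

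On WPI the step to FAT-40 raised interferon genes, among them the chemokines Cxcl9 (1.26 ± 0.27, adjusted p = 4e-04, 12 of 12 libraries above the FAT-20 median) and Cxcl10 (1.35 ± 0.30, adjusted p = 0.00071) and Oasl1 (0.82 ± 0.17). Of their list 29 of 47 rose and 0 fell (34 and 0 over the list alone, camera adjusted p = 1.3e-10, 0.53 with estimated correlation). Of the T cell genes (Cd8a 0.54 ± 0.16, Cd3g 0.50 ± 0.14) 8 of 18 rose and 0 fell (13 and 0 over the list alone, camera adjusted p = 7.4e-05, 0.53 with estimated correlation). Apoa4 (1.02 ± 0.22) and Slc27a4 (0.59 ± 0.10) rose, and lipogenic Thrsp (-2.0 ± 0.29), Gpam (-0.46 ± 0.07) and Synm of smooth muscle (-1.04 ± 0.21) fell. Reg3g (-0.51 ± 0.51, adjusted p = 0.48) did not pass. Altogether 2163 genes were higher and 2215 lower, and 39 with the adipose and smooth muscle scores in the model.

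No jejunal gene passed the test of whether the FAT-55 response differed between WPI and CAS by edgeR, with 1016 genes at an unadjusted p under 0.05 and 4 genes called by DESeq2. Reg3g had a difference of -1.24 ± 0.74, adjusted p = 0.86, Apoa4 0.28 ± 0.32, adjusted p = 0.95 and the immediate early gene Egr1 -2.44 ± 0.57, adjusted p = 0.17. For macrophages and dendritic cells, a list that camera called, 0 of 19 were more positive and 0 more negative (4 and 0 over the list alone, camera adjusted p = 7.3e-09, 0.16 with estimated correlation), with Csf1r at 0.65 ± 0.17, adjusted p = 0.24.

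In liver, averaged over fat levels, WPI lowered genes that make and store fat. Scd1, the desaturase that makes monounsaturated fatty acids (ENSMUSG00000037071, chromosome 19, 44394455 to 44407879), fell (-1.17 ± 0.17, adjusted p = 2.6e-06) and lay below the CAS median of its fat level in 35 of 36 WPI libraries. Elovl5, a fatty acid elongase (-0.72 ± 0.11, adjusted p = 3.3e-06), and Acacb, the acetyl-CoA carboxylase at mitochondria (-1.08 ± 0.17, adjusted p = 6e-06), fell with it. Of the lipogenesis list 10 of 22 fell and 0 rose (13 and 0 over the list alone, camera adjusted p = 8e-09, 0.11 with estimated correlation). Cidec, a lipid droplet protein that enlarges droplets (ENSMUSG00000030278, chromosome 6, 113424634 to 113435760), fell (-1.57 ± 0.25, adjusted p = 6e-06, 30 of 36 libraries below), as did Mogat1, a triglyceride synthesis enzyme (-1.04 ± 0.22, adjusted p = 0.00062), and the adipogenic receptor Pparg (-0.52 ± 0.13, adjusted p = 0.0025). Of the lipid droplet list 8 of 22 fell and 0 rose (11 and 1 over the list alone, camera adjusted p = 1.4e-05, 0.16 with estimated correlation). Glutathione transferases Gstm3 (-1.59 ± 0.13, adjusted p = 4.3e-14, 35 of 36 libraries below), Gstm1 (-0.57 ± 0.07) and Gstm4 (-0.56 ± 0.07) fell, and Col3a1 of collagen was lower (-0.46 ± 0.13).

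Higher on WPI were the trefoil peptide Tff3 (2.07 ± 0.46, adjusted p = 0.00085), asparagine synthetase Asns (1.83 ± 0.39, adjusted p = 0.00054, 25 of 36 libraries above the CAS median) and Hsd3b5, a steroid dehydrogenase typical of male mouse liver (1.45 ± 0.39, adjusted p = 0.006, 22 of 36 above). At FAT-20 the Hsd3b5 mean was lower on WPI (84.3 ± 40.1 CPM) than on CAS (149 ± 60.5). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose (0.70 ± 0.18, adjusted p = 0.0038, 32 of 36 above), together with the bile acid importer Slc10a1 (0.37 ± 0.05, adjusted p = 5.5e-07), the bile acid receptor Nr1h4 (0.27 ± 0.05) and Cyp7b1 (0.62 ± 0.13, 21 of 36 above). Cyp4a31 (1.18 ± 0.14, adjusted p = 3.5e-08), Cyp4a14 (0.63 ± 0.12) and Hadhb (0.20 ± 0.04) rose among fatty acid oxidation and PPARα target genes, of which 12 of 29 rose and 2 fell (15 and 2 over the list alone, camera adjusted p = 6e-06, 0.52 with estimated correlation). Cytosolic ribosomal protein genes rose by small amounts, with Rps27 at 0.34 ± 0.05 and Rpsa at 0.26 ± 0.04. Of the ribosomal protein genes 73 of 77 rose and 0 fell (75 and 0 over the list alone, camera adjusted p = 1.1e-50, 0.11 with estimated correlation). Cpt1a (-0.03 ± 0.06, adjusted p = 0.75) and the hepatokine Fgf21 (-0.16 ± 0.22, adjusted p = 0.7) did not pass. In all 1069 genes were higher and 1138 lower of 15051 tested, and 711 in total when counts were summed by identifier stem.

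At FAT-20, 33 liver genes were higher and 44 lower on WPI. Mt1 (2.04 ± 0.40, adjusted p = 0.0069) and Mt2 (2.83 ± 0.61, adjusted p = 0.016), the transcription factor Cux2 (2.5 ± 0.49, adjusted p = 0.0069, 8 of 12 libraries above the CAS median) and Sult2a7 (0.99 ± 0.25) were higher. Lepr, the leptin receptor (-0.91 ± 0.19, adjusted p = 0.015), the adipokine Serpina12 (-1.34 ± 0.24, adjusted p = 0.002), the steroid reductase Srd5a1 (-0.52 ± 0.13) and Hspb6 (-0.37 ± 0.07) were lower. Scd1 (-0.64 ± 0.30, adjusted p = 0.34) and Cyp7a1 (0.47 ± 0.31, adjusted p = 0.53) did not pass. The count of 77 was 0 for sums by identifier stem, 155 by DESeq2, 515 with sample quality weights and 165 without WPI FAT-55 replicate 2.

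At FAT-40, 579 genes were higher and 657 lower on WPI. Moxd1, a monooxygenase-like protein (8.87 ± 1.2, adjusted p = 1e-06, 9 of 12 libraries above the CAS median), Asns (3.80 ± 0.65, adjusted p = 7.5e-05, 8 of 12) and Cyp4a31 (2.07 ± 0.25, adjusted p = 7.1e-08, 12 of 12) were higher. Scd1 (-1.34 ± 0.30, adjusted p = 0.0024), Acacb (-1.43 ± 0.29), Cidec (-1.76 ± 0.43) and the cytochrome Cyp2c55 (-1.69 ± 0.25) fell. Of the lipogenesis list 10 of 22 fell and 0 rose (14 and 0 over the list alone, camera adjusted p = 3.2e-10, 0.16 with estimated correlation). Acute phase genes Apcs (1.09 ± 0.26) and Itih3 (0.64 ± 0.15, 9 of 12 above) rose. Of their list 9 of 26 rose and 0 fell (13 and 0 over the list alone, camera adjusted p = 2.6e-06, 0.32 with estimated correlation). Sums by identifier stem left 64 genes.

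Of the 3 fat levels FAT-55 gave the most called liver genes between the proteins, where 1064 genes were higher and 1119 lower on WPI. Genes of stellate cells and scar tissue were lower, with the protease inhibitor Timp1 at -1.95 ± 0.38, adjusted p = 3e-04, collagen Col1a2 at -1.10 ± 0.22, adjusted p = 0.00051 and the crosslinking enzyme Loxl2 at -0.74 ± 0.15, adjusted p = 0.00059. Of the stellate cell and fibrosis genes 7 of 14 fell and 0 rose (9 and 0 over the list alone, camera adjusted p = 1.1e-07, 0.25 with estimated correlation). Timp1 lay below the CAS median in 12 of 12 libraries. Monocyte and macrophage genes Ccr2 (-1.21 ± 0.24), Itgax (-1.34 ± 0.27) and Gpnmb (-2.0 ± 0.47) fell. Of the macrophage genes 4 of 22 fell and 0 rose (8 and 0 over the list alone, camera adjusted p = 0.0071, 0.61 with estimated correlation). Cidec (-2.45 ± 0.43, adjusted p = 7.7e-05), Plin4 (-1.43 ± 0.33), Scd1 (-1.55 ± 0.31, adjusted p = 4e-04) and Elovl5 (-0.98 ± 0.19) fell. Of the lipid droplet list 10 of 22 fell and 0 rose (11 and 2 over the list alone, camera adjusted p = 0.00016, 0.25 with estimated correlation). Hsd3b5 (3.56 ± 0.74, adjusted p = 0.00072, or a log2 ratio of means of 4.46 without CAS FAT-55 replicate 3), Cyp4a12b (2.13 ± 0.46) and Cyp2c54 (1.90 ± 0.27) rose, as did Cyp7a1 (0.93 ± 0.31, adjusted p = 0.035), the transporter Slco1a1 (1.63 ± 0.36) and Igf1, a growth hormone target (0.43 ± 0.10). Ribosomal protein genes were higher too, with Rpl27a at 0.40 ± 0.07. Among all ribosomal protein genes 70 of 77 rose and 0 fell (74 and 0 over the list alone, camera adjusted p = 4.1e-33, 0.25 with estimated correlation). Sums by identifier stem left 211 genes.

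**Figure D3:**
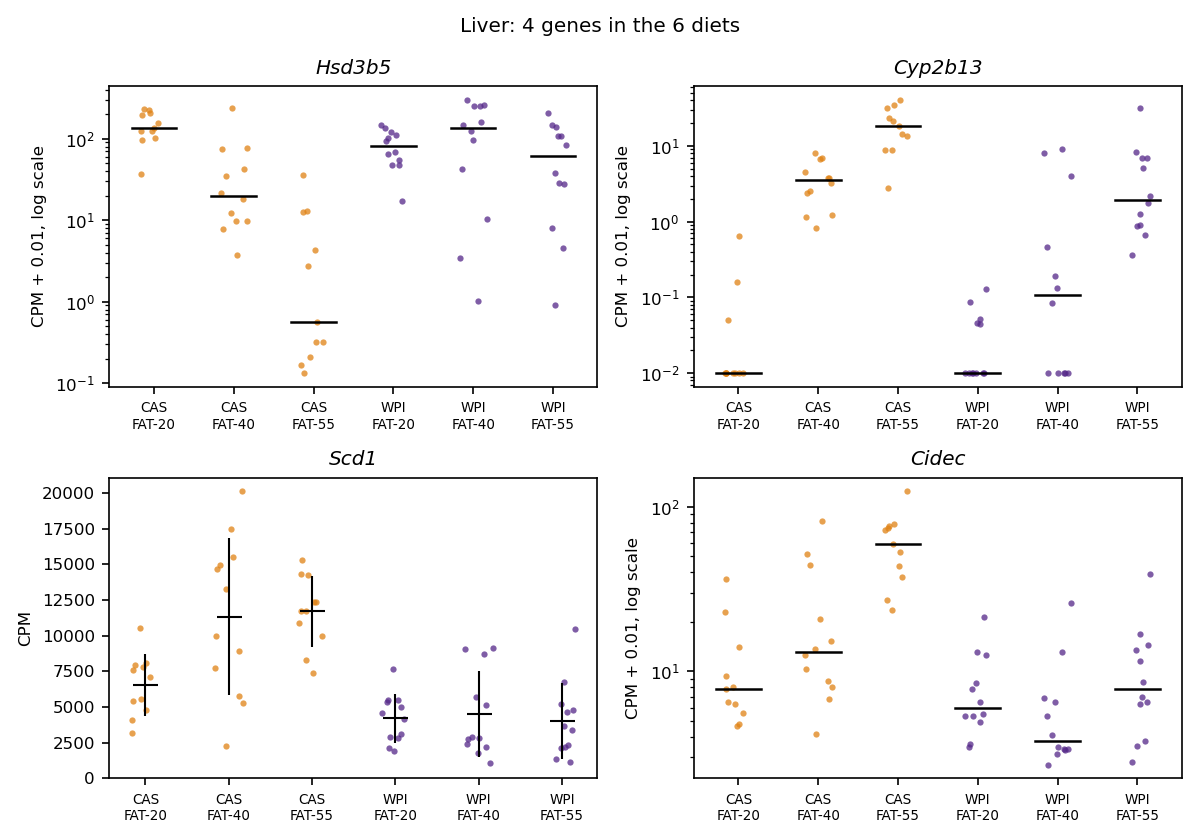
CPM of Hsd3b5, Cyp2b13 and Cidec (log scale, 0.01 added, lines at medians) and of Scd1 (bars give the mean ± SD) in the 6 diets, with 1 point per liver library and 11 or 12 libraries per diet. The CAS FAT-55 libraries held the lowest Hsd3b5 and the highest Cyp2b13 medians of the 6 diets.

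On CAS, FAT-55 against FAT-20 switched liver genes over wide ranges. Cyp2b13 (7.95 ± 0.93, adjusted p = 3.3e-10) rose from a mean of 0.0761 ± 0.194 CPM (SD, n = 11) to 19.9 ± 12 (SD, n = 11) and Cyp2b9 (6.93 ± 0.93, adjusted p = 1.5e-08) rose with it, both cytochromes typical of female mouse liver. Without CAS FAT-20 replicate 5 (0.645 CPM of Cyp2b13) their log2 ratios of means were 10.02 and 8.23. Hsd3b5 (ENSMUSG00000038092, chromosome 3, 98618634 to 98630252) fell (-4.55 ± 0.78, adjusted p = 3e-06) from 149 ± 60.5 to 6.33 ± 10.8 CPM, and 11 of 11 FAT-55 libraries lay below the FAT-20 median (log2 ratio of means -5.44 without CAS FAT-55 replicate 3). The droplet proteins and enzymes Cidea (6.05 ± 0.96, adjusted p = 6.2e-07), Mogat1 (3.36 ± 0.40, adjusted p = 8e-10), Pparg (1.68 ± 0.23, adjusted p = 2.6e-08) and Cd36 (2.42 ± 0.28, adjusted p = 2.4e-10) rose. Of the lipid droplet list 11 of 22 rose and 5 fell (11 and 5 over the list alone, camera adjusted p = 0.012, 0.5 with estimated correlation). Srebf1 (1.36 ± 0.23), Pgd (0.85 ± 0.10) and Scd1 (0.84 ± 0.31, adjusted p = 0.024) rose in lipogenesis. PPARα targets fell, with Cyp4a31 at -3.18 ± 0.27, adjusted p = 3.8e-14, Ehhadh at -1.86 ± 0.19, adjusted p = 3.6e-12 and Hadhb at -0.61 ± 0.06. Of the PPARα and oxidation genes 1 of 29 rose and 20 fell (1 and 21 over the list alone, camera adjusted p = 8.1e-13, 0.31 with estimated correlation).

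Fibrosis genes rose together, Col3a1 by 1.90 ± 0.25, adjusted p = 5.4e-09 and Col1a2 by 1.76 ± 0.24. Among all stellate cell and fibrosis genes 12 of 14 rose and 0 fell (12 and 0 over the list alone, camera adjusted p = 2.5e-07, 0.31 with estimated correlation). Macrophage genes Gpnmb (3.60 ± 0.56), Itgax (1.93 ± 0.29) and Ccr2 (1.72 ± 0.26) rose. Among all macrophage genes 12 of 22 rose and 0 fell (13 and 0 over the list alone, camera adjusted p = 0.00019, 0.5 with estimated correlation). Interferon genes Ifit2 (0.96 ± 0.16) and Ifih1 (0.48 ± 0.08) rose. Among all interferon response genes 30 of 47 rose and 0 fell (30 and 0 over the list alone, camera adjusted p = 2.5e-07, 0.5 with estimated correlation). In the xenobiotic list, led by Gstm3 (2.93 ± 0.25, adjusted p = 3.8e-14) and Gstm2 (1.55 ± 0.18), 19 of 33 rose and 4 fell (19 and 4 over the list alone, camera adjusted p = 7.6e-06, 0.31 with estimated correlation). All of the ribosomal protein genes fell, with Rps27a at -0.57 ± 0.08. Of the ribosomal protein genes 77 of 77 fell and 0 rose (77 and 0 over the list alone, camera adjusted p = 2.3e-34, 0.31 with estimated correlation). The growth axis genes Igfbp2 (-1.78 ± 0.23) and Igf1 (-0.55 ± 0.10) fell. The acute phase protein Orm3 (3.86 ± 0.39, adjusted p = 6.3e-12) and Hao2 (5.40 ± 0.70) rose, while Slco1a1 (-2.75 ± 0.38) and Slc10a1 (-0.58 ± 0.09) fell. Cyp7a1 (-0.59 ± 0.32, adjusted p = 0.13) and Fgf21 (-0.52 ± 0.39, adjusted p = 0.28) did not pass. A total of 3398 genes were higher and 3122 lower.

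On WPI the step from FAT-20 to FAT-55 raised Cyp2b13 (7.56 ± 1.06, adjusted p = 1.6e-07), Cyp2b9 (4.56 ± 0.79, adjusted p = 8.7e-06) and Mogat1 (2.10 ± 0.40) and lowered Moxd1 (-4.01 ± 0.98, adjusted p = 0.0014), Tff3 (-3.17 ± 0.69) and Cux2 (-3.69 ± 0.51). Cyp2b13 lay above the FAT-20 median in 12 of 12 libraries, with a log2 ratio of means of 6.96 without WPI FAT-55 replicate 7 and 8.35 without WPI FAT-20 replicate 9. PPARα targets Ehhadh (-2.02 ± 0.18, adjusted p = 5.2e-13), Cyp4a31 (-2.74 ± 0.25, adjusted p = 1.5e-12) and Cyp4a14 (-1.65 ± 0.21) fell. Among all PPARα and oxidation genes 12 of 29 fell and 0 rose (12 and 0 over the list alone, camera adjusted p = 9.3e-07, 1 with estimated correlation). Ribosomal protein genes fell, with Rps28 at -0.42 ± 0.09. Among all ribosomal protein genes 50 of 77 fell and 0 rose (61 and 0 over the list alone, camera adjusted p = 1.6e-17, 1 with estimated correlation). Interferon genes Ifit3 (0.91 ± 0.18) and Isg15 (0.71 ± 0.16) rose. Of the interferon response genes 18 of 47 rose and 2 fell (19 and 2 over the list alone, camera adjusted p = 6.3e-05, 1 with estimated correlation). The chaperones Calr (0.61 ± 0.12) and Pdia6 (0.57 ± 0.12) rose. The urea cycle enzyme Otc (0.44 ± 0.06) and Mccc1 of leucine breakdown (0.46 ± 0.07) rose, and Scd1 was -0.07 ± 0.30, adjusted p = 0.89. In total 2200 genes were higher and 1805 lower, and sums by identifier stem left 2171.

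At FAT-40 on CAS, PPARα targets fell, with Cyp4a31 at -3.43 ± 0.27, adjusted p = 8.6e-16, Cyp4a14 at -2.59 ± 0.22, adjusted p = 3.7e-14 and Ehhadh at -2.11 ± 0.18. Of the PPARα and oxidation genes 25 of 29 fell and 0 rose (27 and 0 over the list alone, camera adjusted p = 1.8e-29, 0.012 with estimated correlation). Lipogenic genes rose, with Srebf1 at 1.99 ± 0.23, adjusted p = 4e-10, Fasn at 1.80 ± 0.25, adjusted p = 8.1e-08 and Pgd at 0.81 ± 0.10. Of the lipogenesis genes 17 of 22 rose and 0 fell (17 and 0 over the list alone, camera adjusted p = 2.4e-08, 0.19 with estimated correlation). Hibadh (0.49 ± 0.07) and Haao (0.45 ± 0.07) of amino acid breakdown rose. Fgf21 fell (-1.15 ± 0.39, adjusted p = 0.018), Moxd1 fell (-6.52 ± 1.21) and ribosomal protein genes fell, with Rps18 at -0.48 ± 0.07. Of the ribosomal protein genes 72 of 77 fell and 0 rose (75 and 0 over the list alone, camera adjusted p = 1.6e-33, 0.35 with estimated correlation). In all 2372 genes were higher and 2168 lower.

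The same fat step on WPI lowered PPARα targets, with Ehhadh at -1.83 ± 0.18, adjusted p = 2.9e-11, Cyp4a14 at -1.97 ± 0.21 and Acot1 at -1.66 ± 0.20. Among all PPARα and oxidation genes 15 of 29 fell and 0 rose (21 and 0 over the list alone, camera adjusted p = 1.9e-32, 0.0062 with estimated correlation). Fasn (1.04 ± 0.24), Srebf1 (0.92 ± 0.21) and Acly (0.46 ± 0.15) rose, while the immediate early gene Egr1 fell (-2.30 ± 0.49). Cyp2b13 (5.95 ± 1.18), Hao2 (3.09 ± 0.63) and Orm3 (1.77 ± 0.35) were called higher, in 7 of 12, 8 of 12 and 11 of 12 libraries above the FAT-20 median. Cyp2b13 rested on WPI FAT-40 replicates 12, 11 and 5 (9.06, 7.99 and 4.03 CPM, the others at most 0.451), and its log2 ratio of means was 5.50 without replicate 12 and 6.74 without WPI FAT-20 replicate 9, in place of 6.15. Fgf21 was -0.16 ± 0.38, adjusted p = 0.87. Here 631 genes were higher and 353 lower, and sums by identifier stem left 58.

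The liver response to FAT-55 differed between the proteins at 1027 genes, 452 with a more positive and 575 with a more negative change on WPI. Hsd3b5 (difference 4.38 ± 0.98, adjusted p = 0.0041, or 5.28 without CAS FAT-55 replicate 3), Serpina1e (2.58 ± 0.75, adjusted p = 0.027), the adhesion receptor Adgrf1 (2.91 ± 0.56, adjusted p = 0.0012), Slco1a1 (2.12 ± 0.50) and Slc10a1 (0.63 ± 0.13) had more positive changes on WPI. More negative ones were measured for Ly6d (-3.31 ± 0.54, adjusted p = 0.00018), the iron-binding Lcn2 (-3.09 ± 0.74, adjusted p = 0.0076, or -3.83 without CAS FAT-20 replicate 9), the matrix protein Thbs1 (-2.42 ± 0.51, adjusted p = 0.0026) and Gstm3 (-1.92 ± 0.33, adjusted p = 0.00027). Fibrosis genes shared that direction, with Col1a2 at -1.45 ± 0.32, adjusted p = 0.0041, Loxl2 at -1.04 ± 0.22 and the basement membrane collagen Col4a1 at -0.95 ± 0.21. Of the stellate cell and fibrosis genes 8 of 14 were more negative and 0 more positive (12 and 0 over the list alone, camera adjusted p = 1.5e-10, 0.15 with estimated correlation). Macrophage genes Spp1 (-0.80 ± 0.24) and Cd68 (-0.62 ± 0.20) and the lipid genes Cd36 (-1.31 ± 0.37), Plin4 (-1.66 ± 0.46) and Apoa4 (-1.73 ± 0.46) did as well. Among PPARα targets Creb3l3 (0.42 ± 0.08) and Eci2 (0.52 ± 0.12) were more positive. Of the PPARα and oxidation genes 8 of 29 were more positive and 0 more negative (13 and 0 over the list alone, camera adjusted p = 1.4e-05, 0.5 with estimated correlation). Sums by identifier stem gave 2 called genes and a random effect for stem 110.

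In hypothalamus the 4 feeding neuropeptide genes fixed as references did not pass between proteins averaged over fat levels. Agrp, which drives feeding, was -0.08 ± 0.14, adjusted p = 0.76, its partner Npy 0.16 ± 0.07, adjusted p = 0.26, the satiety precursor Pomc -0.26 ± 0.19, adjusted p = 0.43 and Cartpt -0.04 ± 0.10, adjusted p = 0.81. WPI lowered Adnp (-1.17 ± 0.12, adjusted p = 1e-11), the transcription factor Cebpb (-1.08 ± 0.10, adjusted p = 7.8e-13), Tmem158 (-0.78 ± 0.07, adjusted p = 1.1e-12), Foxd1 (-0.76 ± 0.12, adjusted p = 7.1e-06) and Glcci1 (-0.70 ± 0.11). The leptin signalling inhibitor Socs3 (-0.34 ± 0.09, adjusted p = 0.035), the oligodendrocyte lineage factor Olig2 (-0.23 ± 0.05, adjusted p = 0.00074) and Egr4 (-0.59 ± 0.15) were lower too. Except for Socs3 these genes hold a 500-base stretch of 74.6 to 81.8% GC, and the rank correlation of log2 fold change with that GC content was -0.45 over all genes. Adnp, Cebpb, Tmem158, Foxd1, Glcci1 and Egr4 lay below the CAS median in 22 of 34, 26 of 34, 23 of 34, 25 of 34, 23 of 34 and 25 of 34 libraries, and at FAT-40 Adnp had a mean of 119 ± 32.1 on WPI and 94.2 ± 19.4 on CAS, and their differences were largest at FAT-55. Slitrk6 (0.49 ± 0.11, adjusted p = 0.0051), Kitl (0.40 ± 0.11, 25 of 34 above) and Cox6a2 (0.54 ± 0.15) were higher. In all 48 genes were higher and 271 lower of 14830 tested, and sums by identifier stem left 51.

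At FAT-20 only Skp2 was higher (0.61 ± 0.14, adjusted p = 0.014) and 149 genes were lower by limma, among them Phlda1 (-0.58 ± 0.15, adjusted p = 0.034) and Arhgap45 (-0.55 ± 0.14). DESeq2 called 33 genes and edgeR on recovered reads 6, and without the 10 libraries whose median correlation with the others lay under 0.97 the count was 12. EdgeR with median-of-ratios scaling left 1, and sums by identifier stem and a random effect for stem 0.

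At FAT-40 limma called 0 genes, with 414 at an unadjusted p under 0.05, and DESeq2 and edgeR also called 0, while sample quality weights gave 21.

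At FAT-55, 304 genes were higher and 574 lower on WPI. Adnp (ENSMUSG00000051149, chromosome 2, 168180986 to 168207112) fell (-3.38 ± 0.20, adjusted p = 1.5e-22), from a mean of 89.5 ± 24.1 (SD, n = 11) to 8.16 ± 4.68 (SD, n = 12) reads after size factors, and 12 of 12 WPI libraries lay below the CAS median. Cebpb (ENSMUSG00000056501, chromosome 2, 167688915 to 167690418; -3.16 ± 0.17, adjusted p = 3.1e-24, 12 of 12 below), Tmem158 (-2.23 ± 0.12, adjusted p = 1.4e-23, 12 of 12 below), Scand1 (-2.70 ± 0.30, adjusted p = 1.8e-10), Glcci1 (-2.38 ± 0.19, adjusted p = 1.4e-16) and Mapkapk5 (-2.25 ± 0.25, adjusted p = 6.3e-11) fell. These genes hold GC-rich stretches. Of the 1511 genes whose most GC-rich 500 bases had at least 71.4% GC, 26.1% were called lower (395 genes), against 1.34% of the others (178 of 13313). Klf2 (-1.08 ± 0.17), Ier5 (-0.65 ± 0.09), Egr4 (-1.18 ± 0.25) and Dbp (-0.50 ± 0.13) fell, and belong to those GC-rich genes with 73.8 to 79% GC. For immediate early genes 3 of 21 fell and 0 rose (3 and 0 over the list alone, camera adjusted p = 0.0014, 0.78 with estimated correlation). Markers of thalamus, which borders the dissected region, rose, with Tnnt1 at 1.43 ± 0.38, adjusted p = 0.012. Of the thalamus genes 4 of 9 rose and 0 fell (8 and 0 over the list alone, camera adjusted p = 0.00018, 0.78 with estimated correlation). Gabrd (1.39 ± 0.32) and Gbx2 (1.14 ± 0.33) rose also, while Agrp (-0.01 ± 0.25, adjusted p = 0.99) and Npy (0.21 ± 0.12, adjusted p = 0.31) did not pass. Sums by identifier stem left 258 genes. Of the called genes 34.6% were higher, against 12.1% by edgeR with median-of-ratios scaling and 62.9% (1692 higher, 998 lower) without the 10 libraries of low correlation.

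**Figure D4:**
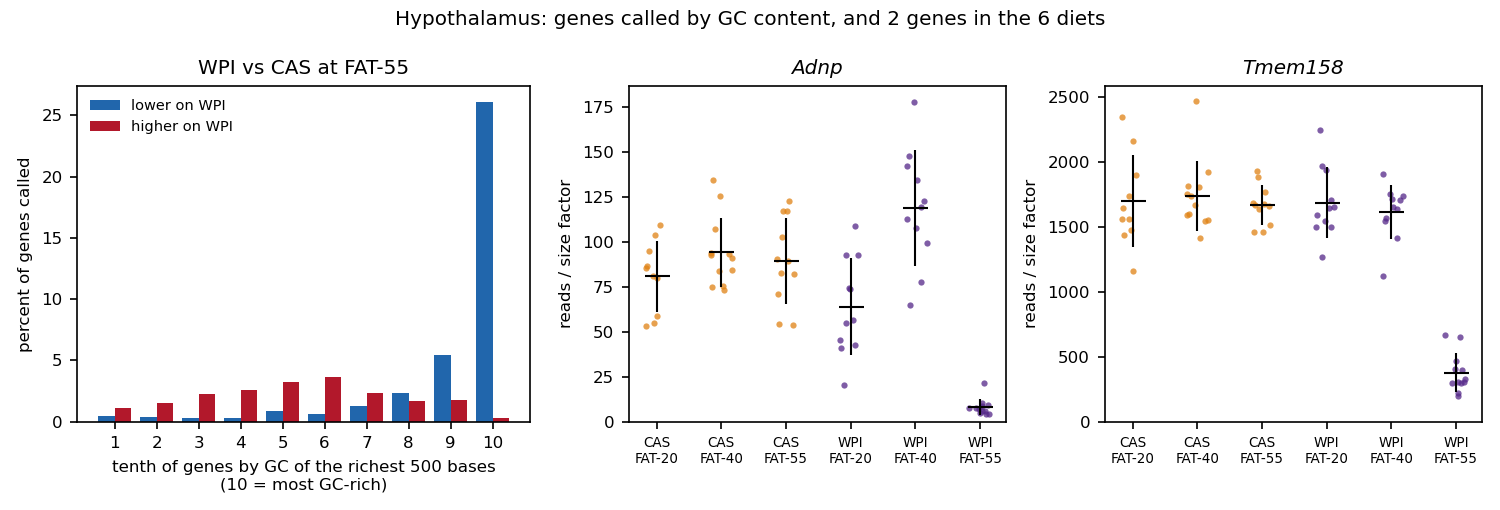
Percent of genes called lower or higher on WPI at FAT-55 (left) in 10 classes of genes by the GC content of their most GC-rich 500 bases, and reads after size factors of Adnp and Tmem158 in the 6 diets, with 1 point per hypothalamus library, 10 to 12 libraries per diet and bars at the mean ± SD. The most GC-rich class held 26.1% lower and 0.331% higher genes.

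FAT-55 against FAT-20 on CAS raised the immediate early genes Fos (0.64 ± 0.15, adjusted p = 0.019), Jun (0.41 ± 0.09, adjusted p = 0.02) and Fosb (0.74 ± 0.20) in hypothalamus, where 3 of 21 rose and 0 fell (11 and 0 over the list alone, camera adjusted p = 3.1e-05, 0.62 with estimated correlation). Tmsb10 (-1.47 ± 0.26, adjusted p = 0.00048), Sdhc of respiratory complex II (-0.68 ± 0.14, adjusted p = 0.0076) and mt-Co3 (-0.86 ± 0.20, adjusted p = 0.02) fell. Ribosomal protein genes had a median of -0.93. Among all ribosomal protein genes 4 of 77 fell and 0 rose (74 and 0 over the list alone, camera adjusted p = 3.1e-22, 0.62 with estimated correlation), with Rps27 at -0.94 ± 0.23. Intestinal Fcgbp was higher (1.56 ± 0.39, adjusted p = 0.029). Npy (-0.43 ± 0.13, adjusted p = 0.052) and Agrp (-0.45 ± 0.26, adjusted p = 0.19) did not pass. Of 10 CAS FAT-20 libraries, 3 had a median correlation with the other libraries under 0.97, against 0 of 11 on CAS FAT-55, and log2 fold change rose with transcript length (rho 0.56). In all 189 genes were higher and 157 lower (54.6% higher, and 20.8% of 2529 by edgeR with median-of-ratios scaling), and 145 were called without the 10 libraries of low correlation. Sums over identifier stems left 4 called genes and a random effect for stem 6.

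On WPI, FAT-55 lowered Npy (-0.35 ± 0.12, adjusted p = 0.023), vasopressin Avp (-0.68 ± 0.22, adjusted p = 0.014) and corticotropin-releasing hormone Crh (-0.44 ± 0.16) against FAT-20. Of the neuropeptide list 6 of 30 fell and 0 rose (0 and 0 over the list alone, camera adjusted p = 0.00081, 0.94 with estimated correlation). The leptin signalling genes Stat3 (0.51 ± 0.11, adjusted p = 3e-04) and Socs3 (0.66 ± 0.16, adjusted p = 0.0015) and the phosphatase Ptpn1 (0.33 ± 0.07) rose. The astrocyte genes Aldh1l1 (0.37 ± 0.06) and Slc1a2 (0.52 ± 0.14), the synaptic gene Syt1 (0.31 ± 0.09) and the clock gene Nr1d1 (0.49 ± 0.11) rose. Adnp (-2.82 ± 0.20, adjusted p = 1.4e-18), Cebpb (-2.62 ± 0.17, adjusted p = 4.9e-20), Cox11 (-2.52 ± 0.22) and Tmem158 (-2.23 ± 0.12) fell. Ribosomal protein genes had a median of -0.59, with Rps2 at -0.56 ± 0.21. Of the ribosomal protein genes 3 of 77 fell and 0 rose (1 and 0 over the list alone, camera adjusted p = 4.6e-14, 0.94 with estimated correlation). The intestinal transcripts Zg16 (2.21 ± 0.47, adjusted p = 0.00039) and Fcgbp (2.16 ± 0.37, adjusted p = 1.2e-05) were higher. The median over all genes was 0.10, rho with transcript length was 0.53, and 4373 genes were higher and 866 lower (83.5% higher, and 39.1% of 3147 by edgeR with median-of-ratios scaling). Without the 10 libraries of low correlation, 5 of them WPI FAT-20 and 2 WPI FAT-55, 2753 genes were called, and sums by identifier stem left 478.

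FAT-40 on CAS raised 28 genes and lowered 7 (80.0% higher, and 12.4% of 1511 by edgeR with median-of-ratios scaling). Fos (0.67 ± 0.14, adjusted p = 0.0092), the cell cycle gene Skp2 (0.74 ± 0.13, adjusted p = 0.00073) and Htr4 (0.71 ± 0.17) were higher and mt-Co3 (-0.80 ± 0.19) lower. Log2 fold change rose with transcript length (rho 0.51), and 3 of 10 CAS FAT-20 libraries had low correlation, against 0 of 12 at FAT-40. Without the 10 low libraries 28 genes were called. Zg16 (3.4 ± 0.48, adjusted p = 1.3e-05) and Apoa1 (3.34 ± 0.49, adjusted p = 1.3e-05) of intestine were higher. The 24 intestinal markers summed to 11.4 ± 3.46 CPM (SD, n = 10) at FAT-20 and 20.1 ± 3.62 CPM (SD, n = 12) at FAT-40, against 52700 ± 4690 CPM (SD, n = 70) in jejunum. Sums by identifier stem left 0 genes and a random effect for stem 8.

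On WPI the step to FAT-40 gave 5630 higher and 2161 lower genes (72.3% higher, and 38.4% of 6288 by edgeR with median-of-ratios scaling). The median over all genes was 0.12. Stat3 (0.53 ± 0.11, adjusted p = 0.00054), Socs3 (0.79 ± 0.16, adjusted p = 0.00059) and Jun (0.54 ± 0.09, adjusted p = 8.1e-05) rose, as did Egr1 (0.67 ± 0.17). Of the energy balance list 19 of 31 rose and 0 fell (19 and 0 over the list alone, camera adjusted p = 0.037, 0.79 with estimated correlation). Ribosomal protein genes fell, with Rps19 at -1.53 ± 0.45, adjusted p = 0.0053 and Rpl34 at -1.32 ± 0.36, adjusted p = 0.0035. Among all ribosomal protein genes 76 of 77 fell and 0 rose (76 and 0 over the list alone, camera adjusted p = 3.3e-26, 0.79 with estimated correlation), while for oxidative phosphorylation 54 of 61 fell and 0 rose (59 and 0 over the list alone, camera adjusted p = 9.3e-21, 0.79 with estimated correlation). The neuronal gene Syn1 (0.64 ± 0.16), the oligodendrocyte precursor gene Gpr17 (0.53 ± 0.14) and the endothelial gene Cdh5 (0.75 ± 0.18) rose. Zg16 (4.25 ± 0.48, adjusted p = 3.4e-09) and Apoa1 (3.69 ± 0.48, adjusted p = 2e-07) were higher, or 3.88 and 3.32 without WPI FAT-40 replicate 8 (intestinal markers 139 CPM). Agrp (-0.49 ± 0.25, adjusted p = 0.093) and Pomc (-0.40 ± 0.34, adjusted p = 0.31) did not pass. Without the 10 libraries of low correlation 692 genes were called, and 0 by sums over identifier stems.

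The difference between WPI and CAS in the FAT-55 response was called for 272 genes upward and 247 downward. Of these 52.4% were upward, and 6.01% of 366 by edgeR with median-of-ratios scaling. The median over all genes was 0.13. Cebpb (-2.94 ± 0.25, adjusted p = 1.1e-14), Adnp (-2.95 ± 0.28, adjusted p = 2.6e-12), Scand1 (-2.78 ± 0.44, adjusted p = 6.6e-06), Glcci1 (-2.48 ± 0.27) and Cox11 (-2.46 ± 0.32) had more negative changes on WPI, as did Avp (-1.15 ± 0.32, adjusted p = 0.029), Klf2 (-1.07 ± 0.24) and Ier5 (-0.69 ± 0.13). Kcne4 (1.03 ± 0.27, adjusted p = 0.018), Wnt4 (0.61 ± 0.16, adjusted p = 0.018), St6galnac5 (0.61 ± 0.15) and the microglial receptor Csf1r (0.29 ± 0.08) had more positive ones. Agrp (0.04 ± 0.36, adjusted p = 0.97) and Npy (0.08 ± 0.18, adjusted p = 0.86) did not pass. Sums by identifier stem left 83 genes.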

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

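The 3 patterns weighed in this part were tested only after their results had been seen. The tests for a library apart from its group and for a difference between WPI and CAS in the FAT-55 response had been fixed earlier.

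Hypothalamus CAS FAT-20 was the group with 10 libraries or fewer, and 62 measures were examined in it. Replicate 6 lay apart from the other 9 libraries in 6 of them. Its median correlation with the other hypothalamus libraries was 0.88, it held the lowest value of Nr1d1 (770 reads after size factors) and the highest of Cox11 (674), Rps19 (59068), Tmsb10 (6628) and Tnnt1 (917). Chance sets about 1 in 20 such measures apart, and measures of 1 library are not independent of one another.

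The FAT-55 response differed between WPI and CAS, by a test of the difference itself, for 1027 liver genes and 519 hypothalamus genes. Sums over identifier stems called 2 and 83 genes and a random effect for stem 110 and 121, and 5 and 29 of 100 splits with whole stems exchanged gave as many genes, so these differences are not secure against the stems. In hypothalamus 52.4% were upward, and 6.01% by edgeR with median-of-ratios scaling. In liver the named genes with a more positive change on WPI were Hsd3b5 (4.38, or 5.28 without CAS FAT-55 replicate 3), Adgrf1 (2.91), Serpina1e (2.58), Slco1a1 (2.12), Slc10a1 (0.63), Eci2 (0.52) and Creb3l3 (0.42). Those with a more negative change were Ly6d (-3.31), Lcn2 (-3.09, or -3.83 without CAS FAT-20 replicate 9), Thbs1 (-2.42), Gstm3 (-1.92), Apoa4 (-1.73), Plin4 (-1.66), Col1a2 (-1.45), Cd36 (-1.31), Loxl2 (-1.04), Col4a1 (-0.95), Spp1 (-0.80) and Cd68 (-0.62). In hypothalamus they were Kcne4 (1.03), St6galnac5 (0.61), Wnt4 (0.61) and Csf1r (0.29) upward and Adnp (-2.95), Cebpb (-2.94), Scand1 (-2.78), Glcci1 (-2.48), Cox11 (-2.46), Avp (-1.15), Klf2 (-1.07) and Ier5 (-0.69) downward.

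In hypothalamus 574 genes were lower on WPI than on CAS at FAT-55. Without the 10 libraries of low similarity 998 were lower and 1692 higher (304 before). Only 2 of the 10 (WPI FAT-55) enter this comparison, so poorer RNA cannot be judged from it. Removal of the GC and length trend left the median of the lower genes at -0.32 (573 genes, 329 still called) after -0.46. They were picked as lower in these data, so the trend as whole cause cannot be judged. A loss of GC-rich segments in the WPI FAT-55 libraries may lie behind many of them, because 26.1% of genes in the tenth with the most GC-rich 500 bases were called lower and 0.331% higher, against 1.34% and 2.25% of the others. The rank correlation of log2 fold change with that GC content was -0.41, against 0.06 in jejunum and -0.07 in liver of these diets, and in hypothalamus it was -0.31 at FAT-20, -0.22 at FAT-40 and 0.19, the other sign, for FAT-55 against FAT-20 on WPI, where the called genes were still lower at FAT-55 (median -0.31, 89.7% of 574, against 0.08 and 32.8% on CAS, though their choice used the FAT-55 libraries). The labels give no preparation batch, and an effect of WPI on GC-rich genes stays open as untested.

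In hypothalamus 7791 genes separated FAT-40 from FAT-20 on WPI, and log2 fold change rose with transcript length (rho 0.60). Of the FAT-20 libraries 8 of 21 had low similarity to the others, and without these and 2 WPI FAT-55 libraries 692 genes were called and rho was 0.20. Poorer RNA in those libraries cannot be told apart from diet, because 12 of 100 removals of as many libraries per group, the real one included, left as few genes (median of the 99 others 6614, lowest 58). The count for FAT-55 on WPI went from 5239 to 2753, with 30 of 100 removals leaving as few. A difference between identifier stems cannot be told apart from diet either, since 3247 genes were called with stem as a random effect, between the bounds set for either reading.

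In jejunum 4711 genes separated FAT-55 from FAT-20 on CAS, along with lower adipose and smooth muscle markers. With both marker scores in the model the fat absorption genes called higher had a median of 0.31 with a median SE of 0.13 (0.42 with 0.11 before, 20 genes, 6 still called). For the genes called lower the median went from -0.50 to -0.33. The scores follow the diets (70.4% of the adipose score's variance lay between diets). For both sets a smaller adipose and muscle share therefore cannot be told apart from a change of expression. A thinner layer of fat around the gut, or a different piece of tissue taken, stays open as untested.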

How the results depend on the processing

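The alternatives described above as added later were chosen after the data were seen. In what follows a comparison is named by its short form, with protein for WPI against CAS, CAS or WPI for the fat step on that protein, and interaction for the difference between proteins in the FAT-55 response. Values are numbers of called genes that lay outside 1.5 times the count in the report. The cause was not tested for any of these changes unless stated. The reported counts, in the order average, FAT-20, FAT-40 and FAT-55 protein, CAS FAT-55, WPI FAT-55, CAS FAT-40, WPI FAT-40 and interaction, were 2606, 1058, 97, 629, 4711, 5231, 4264, 4378, 0 in jejunum, 2207, 77, 1236, 2183, 6520, 4005, 4540, 984, 1027 in liver and 319, 150, 0, 878, 346, 5239, 35, 7791, 519 in hypothalamus.

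Sums over identifier stems, with 24 units per tissue in place of 67 to 70 libraries, gave 1250 (average protein), 227 (FAT-20 protein), 12 (FAT-40 protein), 65 (FAT-55 protein), 3411 (WPI FAT-55), 2121 (CAS FAT-40) and 2091 (WPI FAT-40) in jejunum, 711 (average protein), 0 (FAT-20 protein), 64 (FAT-40 protein), 211 (FAT-55 protein), 2171 (WPI FAT-55), 2754 (CAS FAT-40), 58 (WPI FAT-40) and 2 (interaction) in liver, 51 (average protein), 0 (FAT-20 protein), 258 (FAT-55 protein), 4 (CAS FAT-55), 478 (WPI FAT-55), 0 (CAS FAT-40), 0 (WPI FAT-40) and 83 (interaction) in hypothalamus. Fewer samples are part of this fall by the construction of the alternative. A random effect for stem gave 1571 (average protein), 489 (FAT-20 protein), 33 (FAT-40 protein) and 108 (FAT-55 protein) in jejunum, 1207 (average protein), 7 (FAT-20 protein), 490 (FAT-40 protein), 1004 (FAT-55 protein), 249 (WPI FAT-40) and 110 (interaction) in liver, 86 (average protein), 0 (FAT-20 protein), 308 (FAT-55 protein), 6 (CAS FAT-55), 1567 (WPI FAT-55), 8 (CAS FAT-40), 3247 (WPI FAT-40) and 121 (interaction) in hypothalamus.

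DESeq2 gave 177 (FAT-40 protein) and 4 (interaction) in jejunum, 155 (FAT-20 protein) in liver, 33 (FAT-20 protein), 2934 (CAS FAT-55) and 1872 (CAS FAT-40) in hypothalamus. Sample quality weights gave 191 (FAT-40 protein) in jejunum, 515 (FAT-20 protein) in liver, 700 (average protein), 14 (FAT-20 protein), 21 (FAT-40 protein), 3551 (FAT-55 protein), 1398 (WPI FAT-40) and 1798 (interaction) in hypothalamus. Without a filter on low counts the values were 30 (FAT-20 protein), 618 (WPI FAT-40) and 539 (interaction) in liver, 227 (CAS FAT-55) in hypothalamus. Median-of-ratios scaling moved no count of jejunum or liver past 1.5 times and gave 1 (FAT-20 protein), 2529 (CAS FAT-55), 3147 (WPI FAT-55) and 1511 (CAS FAT-40) in hypothalamus. Covariates for markers of neighbouring tissue gave 435 (FAT-40 protein), 2512 (CAS FAT-55), 1066 (WPI FAT-55), 463 (CAS FAT-40) and 1087 (WPI FAT-40) in jejunum, 119 (FAT-20 protein) in liver, 190 (average protein), 20 (FAT-20 protein) and 2551 (CAS FAT-55) in hypothalamus. Of the list results, an estimated correlation called 8 in jejunum, 2 in liver, 1 in hypothalamus and fry 97 in jejunum, 52 in liver, 38 in hypothalamus, where the reported numbers were 154 in jejunum, 100 in liver, 60 in hypothalamus.

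Among the later alternatives, adipose and smooth muscle scores gave 418 (FAT-55 protein), 1185 (CAS FAT-55), 255 (WPI FAT-55), 177 (CAS FAT-40) and 39 (WPI FAT-40) in jejunum, and the clock score 153 (FAT-40 protein) in jejunum, 42 (FAT-20 protein) in liver. Leaving out liver WPI FAT-55 replicate 2 gave 165 (FAT-20 protein) in liver. EdgeR on recovered reads gave 6 (FAT-20 protein), 2486 (CAS FAT-55), 3095 (WPI FAT-55) and 1609 (CAS FAT-40) in hypothalamus, and removal of the GC and length trend 51 (FAT-20 protein), 993 (CAS FAT-55), 3098 (WPI FAT-55), 285 (CAS FAT-40) and 4228 (WPI FAT-40) in hypothalamus. A pseudocount of 10 gave 9 (CAS FAT-40) in hypothalamus. Leaving out the 10 libraries of low similarity gave 560 (average protein), 12 (FAT-20 protein), 2690 (FAT-55 protein), 145 (CAS FAT-55), 2753 (WPI FAT-55), 692 (WPI FAT-40) and 1514 (interaction) in hypothalamus.

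The other counts, 65 of 92 in jejunum, 59 of 83 in liver, 67 of 119 in hypothalamus, lay within 1.5 times. Over all genes that the naming rule selects, 40 of 10958 values in jejunum, 3 of 7020 values in liver, 9 of 10829 values in hypothalamus changed direction, 28 of the jejunum ones with adipose and smooth muscle scores and 6 of the hypothalamus ones with the GC and length trend removed. Genes seen to change direction were not kept in the report. Of the values it prints 987 of 1050 in jejunum, 1221 of 1341 in liver, 994 of 1204 in hypothalamus were on the same side of the threshold, 61, 120, 205 no longer passed and 2, 0, 5 passed only under the alternative. With sums over stems 9 of 105, 62 of 149 and 54 of 93 no longer passed, and with a random effect for stem 5, 36 and 35. For some hypothalamus genes DESeq2 gave no adjusted p, and 88 values in place of 93 entered. A pseudocount of 0.5 and leaving out hypothalamus WPI FAT-40 replicate 8 left 9 of 9 hypothalamus counts within 1.5 times, and leaving out jejunum WPI FAT-20 replicate 9 did so for 9 of 9 jejunum counts. No paired analysis was possible because each diet was given to different mice and replicate numbers only follow the order of the deposited samples. Simulated folds of 1.5 were recovered for 66%, 78% and 55.1% of genes in jejunum, liver and hypothalamus, so a gene not called is not shown to be unchanged.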

Other observations

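The tests of sex-biased genes, of clock genes and of other splits of the libraries were set before their results were seen, and the readings of stems and the camera bound came after.

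Each count of called genes was set against 99 other splits of the libraries, drawn with a fixed seed, with the real count and the highest other given here in that order. In jejunum 1 of 100 splits, the real one, gave as many genes for the protein average (2606 and 40), at FAT-20 (1058 and 356), FAT-40 (97 and 3) and FAT-55 (629 and 242), for FAT-55 on CAS (4711 and 2401) and WPI (5231 and 128) and for FAT-40 on CAS (4264 and 2490) and WPI (4378 and 750). In liver 1 of 100 did so for the average (2207 and 18), FAT-40 (1236 and 438), FAT-55 (2183 and 1293), FAT-55 on CAS (6520 and 10) and WPI (4005 and 426), FAT-40 on CAS (4540 and 119) and WPI (984 and 17) and the difference in response (1027 and 120), and 2 of 100 at FAT-20 (77 and 1007). In hypothalamus it was 1 of 100 at FAT-55 (878 and 199), for FAT-55 on CAS (346 and 1), FAT-40 on CAS (35 and 1) and FAT-40 on WPI (7791 and 6970), and 3 of 100 for the average (319 and 3782) and FAT-55 on WPI (5239 and 8735). Chance can be excluded at a share of 0.05 for these 23 counts only if single mice are exchangeable. With whole stems exchanged it is not excluded for 6 of them, given below.

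Chance cannot be excluded for hypothalamus at FAT-20 (15 of 100 splits, 150 and 9903) and for its difference in response (7 of 100, 519 and 8930). The splits decide nothing for the counts of 0, hypothalamus at FAT-40 (100 of 100, highest other 1) and the difference in jejunum (100 of 100, highest other 131), because each split gives at least 0. By limma 414 hypothalamus genes at FAT-40 and by edgeR 1016 jejunum genes for that difference had an unadjusted p under 0.05, and DESeq2 called 0 and 4. Splits that called several times the real count, as in liver at FAT-20 and in hypothalamus, point to a structure among the libraries other than diet. When whole identifier stems were exchanged, 17 of 27 counts had a share under 0.05. The others, with the number of splits as large and the highest other, were liver at FAT-20 (22 and 2396), FAT-40 on WPI (11 and 3619) and the difference in response (5 and 2034), and hypothalamus for the average (20 and 9671), FAT-20 (54 and 10856), FAT-55 on WPI (12 and 9446), FAT-40 on WPI (6 and 9460) and the difference (29 and 10383), with the 2 counts of 0 again undecided.

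A shift of the sex-biased liver programme with fat was tested on genes not looked at before, because Cyp2b13, Cyp2b9 and Hsd3b5 had changed on CAS between FAT-20 and FAT-55. Of 11 male-biased genes 9 fell and 0 rose, with a median of -1.29 (camera p = 1.1e-07, and 0.013 with an estimated correlation). C8b (-1.84 ± 0.21), Susd4 (-1.50 ± 0.19) and Ugt2b38 (-3.37 ± 0.66) were among them. Of 14 female-biased genes 8 were measured, and 3 rose and 0 fell with a median of 0.38 (camera p = 0.16, and 0.33 with an estimated correlation). Both medians were beyond the bound set against 10000 random lists (percentiles 0 and 99.6), but so was the female-biased one for WPI against CAS at FAT-20 (percentile 100), where 0 of its genes were called, so a camera p under 0.05 with the estimated correlation was asked for as well. The values are consistent with a loss of male-biased expression on CAS at FAT-55, and a gain of female-biased expression cannot be told apart from none. The difference in response between WPI and CAS had a male-biased median of 0.75 with 4 of 11 more positive (C8b 1.26, Susd4 1.27, Cyp2d9 0.75 and Ugt2b1 0.63) and 0 more negative. The labels do not give the sex of the mice.

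The first component of the clock genes, with diet means removed, held 64.5%, 53.3% and 43.9% of their variance in jejunum, liver and hypothalamus. Between jejunum and liver of 70 mice it correlated at r = 0.91 and rho = 0.82 (r = 0.89 without the 2 farthest mice), which suggests that mice differed in clock phase at collection. Within stems r was 0.73 and between the means of 24 stems 0.96, each with adjusted p = 3e-04 when mice were exchanged within stems or stems within diets, the smallest that 10000 permutations can give. Between jejunum and hypothalamus of 63 mice r was 0.42 and rho 0.59 (r = 0.45 without the 2 farthest), and between liver and hypothalamus r was 0.32 and rho 0.42 (r = 0.35 without the 2 farthest). Within stems these r were -0.05 and 0.09 (adjusted p = 0.77 and 0.72) and between 23 stem means 0.58 and 0.43 (adjusted p = 0.0082 and 0.023), so they rested on differences between stems. The tests with stems kept together were added after the scores had been seen.

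In jejunum, liver and hypothalamus 1639, 1416 and 110 genes rose at FAT-55 on both proteins. Genes called higher on CAS but lower on WPI numbered 1, 21 and 4, and the other way round 2, 24 and 5. Over all genes the log2 fold changes on CAS and WPI correlated at r = 0.68, 0.7 and 0.68.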
